A study of Apis mellifera with 27 samples.

How the data were processed

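Polyadenylated RNA of laser-captured mushroom body tissue enriched for small Kenyon cells was sequenced from honey bee foragers with a stranded library kit, per the labels' protocols. The deposited table held raw counts per gene, whole numbers from reads assigned to genes, for the 27 libraries analysed here. The tools Trimmomatic, FastQC, STAR, featureCounts and DESeq2 were named, per the submitters' processing notes, with no versions. The genome build, the annotation and the strand setting of the counting were not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty, and no coordinates are given. How trimming, mapping and the treatment of reads with several matches affected single genes could not be examined from the counts, and genes with near-identical copies, such as Fabp, are uncertain.

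The table held 12319 gene identifiers. Of these, 12166 equalled a symbol of a RefSeq gene table of the assembly Amel_HAv3.1, and 12318 did after removal of a copy suffix. That table was used for names alone. Most identifiers, 11497, consist of LOC and a number with no gene name, and 389 carried a gene symbol, leaving out tRNA and miRNA genes. Each library was assigned to its time point, colony and replicate from its labels. One further library, of 06:00 on day 11 from colony 2, was not analysed here. Total counts ranged from 5589770 to 12277539 per library. A count of 0 allows up to 3 counts, and this floor covers counting error only, since reads without molecular identifiers are not independent molecules. Between libraries of the same colony and time point the chi-square per degree of freedom, over genes with at least 20 counts, ranged from 11.1 to 44.3, so no pair agreed within sampling noise, as repeat deposits of a library would. This does not show whether libraries came from separate animals. Each library entered the tests as 1 sample. The common biological coefficient of variation was 0.179 in colony 1 and 0.375 in colony 2.

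Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the time point as group, which left 9816 genes holding at least 99.97% of the counts of each library. Libraries were scaled by TMM, and all 27 entered a fit with glmQLFit (robust) and glmQLFTest. Colony and time point were terms for the test over the 7 time points, for the contrasts of 14:00 with 02:00, 10:00 with 22:00 and 06:00 of day 12 with 06:00 of day 11, and for colony 2 against colony 1. The cosine test had colony, cosine and sine of a 24 h period, and the interaction tests let time point, or cosine and sine, differ between colonies. Adjusted p-values are Benjamini-Hochberg values over the genes tested, called under 0.05. Log2 differences are edgeR's, first condition minus second, and SE is the size of the log2 difference over the square root of F, except that the SE of a list's median is from a bootstrap of its genes. Principal components used log2 CPM with a prior count of 2.

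Of 22 gene lists written before the data were examined, 10 had at least 2 genes matched, since most identifiers carry no name and product names could not be used. These were core clock, memory signalling, ecdysteroid and juvenile hormone, heat shock and ER chaperones, synaptic vesicle and active zone, neuropeptides, small Kenyon cells, large and middle Kenyon cells, photoreceptor and optic lobe, and gland, fat body and hemolymph. A further 19 lists were written from the gene symbols after the table was seen but before any values were tested, and 28 lists in all had enough tested genes. The list of opsins holds the same 4 genes as the photoreceptor list. Lists were tested by Fisher's exact test (one-sided) for genes called over time or with a cosine, and by camera (limma 3.58.1) with a preset correlation of 0.01 for 3 contrasts, with Benjamini-Hochberg adjustment over the lists.

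Genes were named by a rule written before the data were examined. For time it took the core clock genes, then the 10 called genes with the largest range among those averaging at least 10 CPM whose colony courses correlated above 0.5, those with a gene name first and one without a name only within the first 3 ranks. This can be read as 10 genes with names or as including the first 3 ranks, and both are given. For every other list it took up to 3 called members or up to 2 with values. For each contrast it took the 5 largest increases and decreases among called genes averaging at least 10 CPM, names first, whose libraries did not overlap or, for colony, that differed in 1 direction at all time points, and all genes where fewer were called. For the interactions it took up to 5 genes with the smallest p. A gene that the rule took is not reported here.

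The tests were tested on simulated counts with 200 changed genes drawn from the libraries' means and sizes. Except in the draws without effects given below, both colonies had the same spread per gene. No difference between the colonies' courses was simulated other than the changes tested. Summed fits count such a difference as spread, so their simulated recovery may be too high. With all libraries, 56.7% of genes changed 2-fold were recovered for the time test, 58.2% for the cosine, 52.2% for 14:00 against 02:00 and for 10:00 against 22:00, 58.2% for 06:00 against 06:00, 73.1% for colony, 1.49% for the interaction and 8.96% for the cosine interaction. At 4-fold the interaction test recovered 39.4%. In 4 simulated draws without effects, the interaction test made 0 to 3 calls, the time test 0 to 1 and the others 0. These draws used 1 spread per gene and colony and drew genes independently, so no library could stand apart. They may therefore understate false calls in the real libraries. Alternatives were DESeq2 1.42.0, limma-voom with and without sample quality weights, DESeq2 size factors, no filter, a filter of 1 CPM in at least 14 libraries, no colony term, a replicate block, summed libraries, each colony alone, each library left out in turn, 06:00 of day 11 left out, 3 libraries standing apart left out, and counts thinned to the smallest total. Lists were also tested by camera with an estimated correlation and by fry.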

Results

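Small Kenyon cells are the most numerous intrinsic neurons of the mushroom bodies, the insect brain centres for learning and memory. Polyadenylated RNA was measured in tissue enriched for these cells, collected by laser capture microdissection from honey bee (Apis mellifera) foragers that had been trained to a feeding time. Foragers were taken at 7 time points, 06:00, 10:00, 14:00, 18:00 and 22:00 of day 11 and 02:00 and 06:00 of day 12, from 2 colonies whose experiments were run separately. The 27 libraries comprised 4 per time point, 2 from each colony, apart from 06:00 of day 11, with 2 libraries from colony 1 and 1 from colony 2. The library of 06:00 on day 11 from colony 2, replicate 1, was not analysed here. The labels do not say that replicates came from separate bees, nor do they tie libraries to animals, so p-values measure only the spread between these samples, which may be technical, and would be too small if libraries shared an animal.

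The total count per library ranged from 5589770 to 12277539. The 14 colony 1 libraries held 8732841 to 12277539 counts and the 13 colony 2 libraries 5589770 to 10846551. A count was found for 8483 to 10444 of the 12319 genes per library. Levels below are CPM, counts scaled to the TMM-adjusted library size, given as mean ± SD with n = 4 per time point and n = 3 for 06:00 of day 11. On the first principal component, 3 colony 2 libraries lay far from the others, namely 06:00 day 11 C2R2, 10:00 day 11 C2R1 and 10:00 day 11 C2R2, where C and R give colony and replicate. The next on that axis, 14:00 day 11 C2R1, had a PC1 score of 45.0 and was kept with the rest, which had scores up to 10.7. The choice used PC1 alone: on PC2, 18:00 day 11 C2R1 had a score of 53.7, close to the 53.8 of 10:00 day 11 C2R1, and was kept as well.

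**Figure D1:**
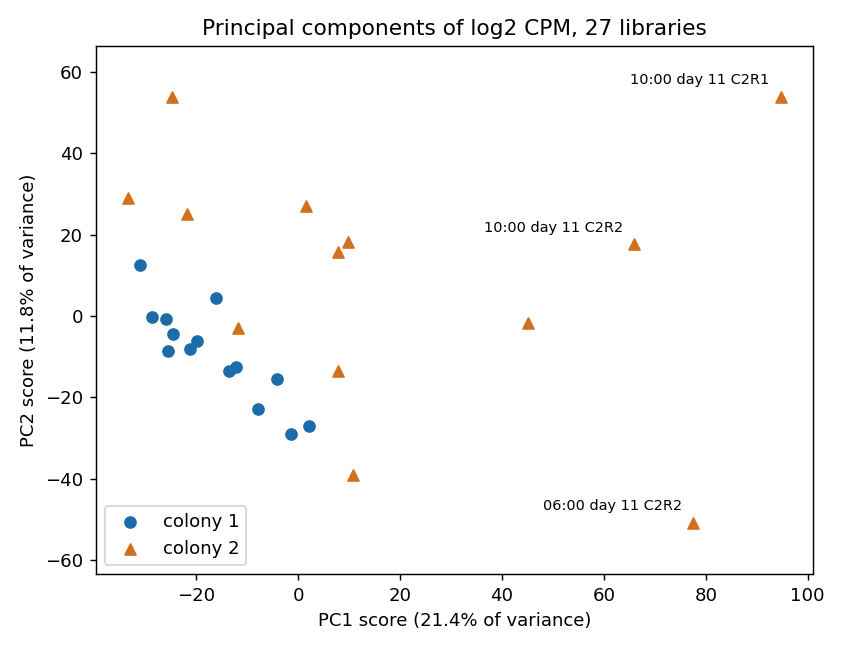
Scores of the 27 libraries on PC1 (21.4% of variance) and PC2 (11.8% of variance) of log2 CPM, with circles for colony 1 and triangles for colony 2. The 3 named colony 2 libraries have PC1 scores of 77.6 (06:00 day 11 C2R2), 94.7 (10:00 day 11 C2R1) and 66.0 (10:00 day 11 C2R2).

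The first comparison asked which transcripts differed among the 7 time points. Of the 8 core clock genes listed, 2 could be matched by name. Cry2, the mammalian-type cryptochrome that represses clock transcription, had its lowest mean at 10:00 (4.20 ± 3.11 CPM) and its highest at 22:00 (25.01 ± 3.86 CPM), but its test over the 7 time points gave an adjusted p of 0.0590 and passed in 10 of 41 alternative runs. Per, its partner in the negative limb of the clock, lay between 21.1 ± 9.23 CPM at 06:00 of day 11 and 34.2 ± 7.84 CPM at 18:00, with adjusted p = 0.356. Hsp90, an abundant chaperone, changed over the day, from 1699 ± 208 CPM at 02:00 to 3688 ± 327 CPM at 10:00 (adjusted p = 0.0205). Adar, which edits adenosines in RNA, changed as well, with 94.1 ± 30.7 CPM at 10:00 and 46.4 ± 5.88 CPM at 02:00 (adjusted p = 0.0124).

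**Figure D2:**
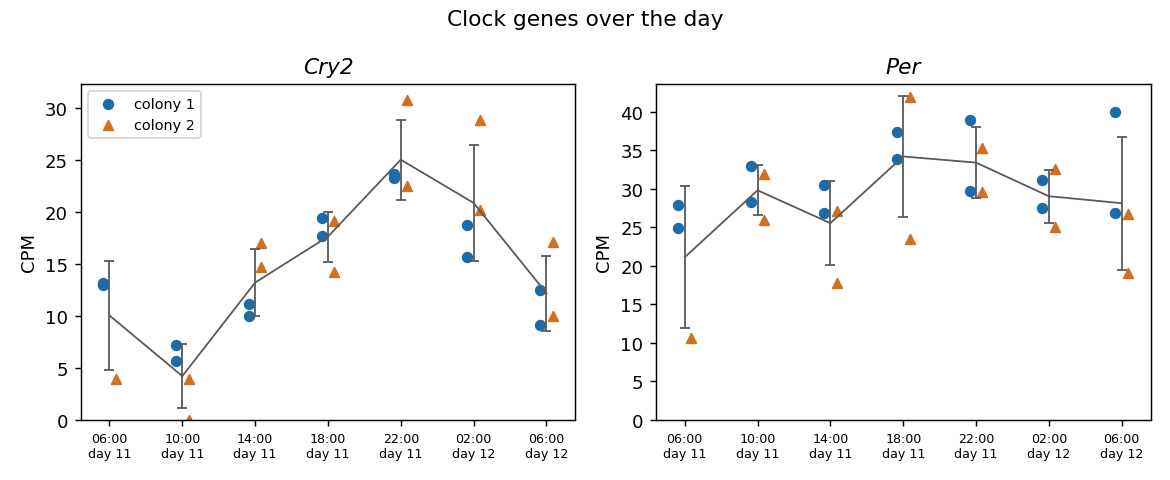
CPM of Cry2 and Per in each library against time point, with circles for colony 1, triangles for colony 2, and lines and bars for the mean ± SD over both colonies. Cry2 runs from 4.20 ± 3.11 CPM at 10:00 to 25.01 ± 3.86 CPM at 22:00, and Per from 21.1 ± 9.23 CPM at 06:00 of day 11 to 34.2 ± 7.84 CPM at 18:00.

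Several of the other named genes that changed had their highest mean at 10:00. These were SIFR, the receptor of the neuropeptide SIFamide (54.4 ± 14.1 CPM at 10:00 and 16.0 ± 4.46 CPM at 06:00 of day 12, adjusted p = 0.0126), Ip3k, a kinase of inositol trisphosphate (81.9 ± 16.1 CPM at 10:00 and 47.1 ± 6.91 CPM at 02:00, adjusted p = 0.0381), and AChE-2, an acetylcholinesterase (1111 ± 415 CPM at 10:00 and 653 ± 61.5 CPM at 06:00 of day 12, adjusted p = 0.0292). Amih had 114 ± 38.2 CPM at 10:00 and 61.6 ± 3.78 CPM at 02:00 (adjusted p = 0.0205). Fabp, a fatty acid-binding protein, had 1171 ± 501 CPM at 10:00 and 532 ± 67.7 CPM at 02:00 (adjusted p = 0.0184). The table holds another Fabp copy, so reads may be split between them.

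Other named genes that changed had their lowest mean at 10:00 or 18:00. rtGEF was at 143 ± 20.3 CPM at 10:00 and 241 ± 20.2 CPM at 02:00 (adjusted p = 0.00496), and SPG11 at 81.8 ± 18.3 CPM at 10:00 and 132 ± 20.2 CPM at 06:00 of day 12 (adjusted p = 0.0407). Uvop, the ultraviolet-sensitive opsin, was at 17.5 ± 11.5 CPM at 10:00 and 42.2 ± 7.34 CPM at 06:00 of day 12 (adjusted p = 0.0417). PDHB, a subunit of pyruvate dehydrogenase, was at 63.2 ± 9.69 CPM at 18:00 and 124 ± 43.3 CPM at 06:00 of day 11 (adjusted p = 0.0270). The latter time includes 06:00 day 11 C2R2, and at 06:00 of day 12 PDHB was at 86.6 ± 13.5 CPM. Its log2 range was 0.98, and as low as 0.44 over 41 alternative runs, of which 8 lost the call. Among the 184 called genes that met the naming rule's level and colony correlation, the largest ranges belonged to genes known by identifier alone. LOC408827 was at 230.2 ± 83.7 CPM at 10:00 and 18.3 ± 8.94 CPM at 02:00, LOC724367 at 101 ± 26.3 and 12.0 ± 4.36 CPM at the same times, and LOC113219162 at 24.3 ± 14.2 CPM at 10:00 and 4.87 ± 1.78 CPM at 06:00 of day 12 (adjusted p = 0.00820, 0.0388 and 0.0388). Over 41 alternative runs, most of which left out a library, the time call was lost in 25 for each of Uvop, SPG11 and LOC724367, in 22 for LOC113219162 and in 21 for Ip3k.

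**Figure D3:**
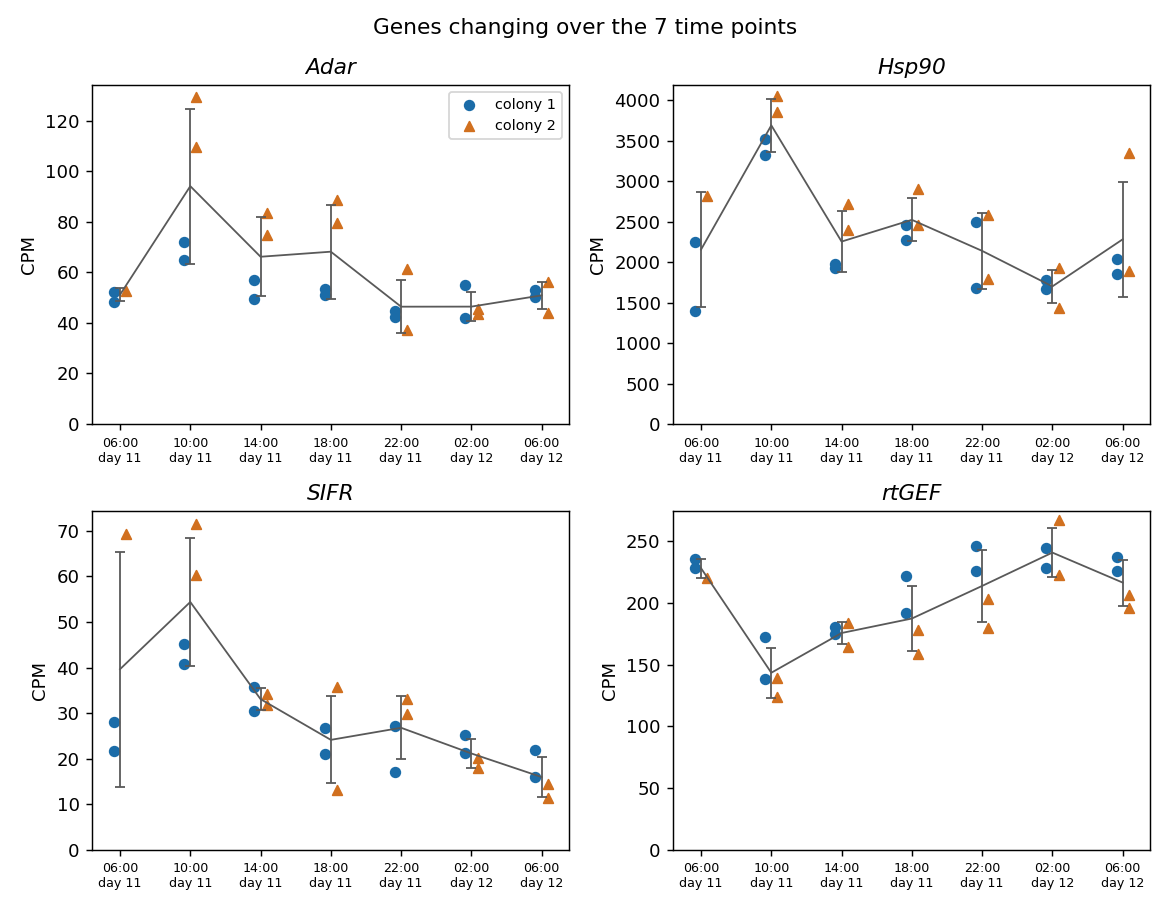
CPM of Adar, Hsp90, SIFR and rtGEF in each library against time point, with circles for colony 1, triangles for colony 2, and lines and bars for the mean ± SD. Adar, Hsp90 and SIFR have their highest mean at 10:00, and rtGEF its lowest.

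In all, 225 of 9816 genes changed over the 7 time points (edgeR's quasi-likelihood test, Benjamini-Hochberg). The count ran from 105 to 569 when 1 library was left out, and was 143 with the replicate block. Of the 225, 101 had their highest and 91 their lowest mean CPM at 10:00. Of the 4 libraries of 10:00, 2 are among the 3 standing apart, and without those 3 libraries 280 genes were called, 144 of them shared with the 225. When the libraries of each colony and time point were summed, edgeR called 0 genes (325 at unadjusted p under 0.05). The summed fit recovered 43.3% of genes given a 2-fold change in simulated data, and 5.97% at 1.5-fold. The simulation held no difference between the colonies' courses. On the 27 libraries DESeq2 called 808 genes and limma-voom 224.

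A 24-h cosine asked which transcripts had a daily course with a single peak. Cry2 fitted one, with its peak at 22.1 h (adjusted p = 0.0186), and Per did not pass (adjusted p = 0.327). Adar peaked at 12.5 h (adjusted p = 0.0103), Fabp at 13.1 h (adjusted p = 0.00457) and rtGEF at 1.05 h (adjusted p = 0.00623). Eaat-2, a glutamate transporter and the single gene of the glia list matched, by a synonym, had a cosine with its peak at 10.8 h (adjusted p = 0.0241). Its mean ran from 43.9 ± 12.5 CPM at 02:00 to 128 ± 40.3 CPM at 10:00. Whether the share of glia in the captured tissue differed between times was not tested. The chaperones Hsc70-3 of the endoplasmic reticulum and Cdc37, a partner of Hsp90, peaked at 13.6 and 11.1 h (adjusted p = 0.0395 and 0.0272), while Hsp90 itself had adjusted p = 0.0536.

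Of 9816 genes, 423 had a cosine (edgeR's quasi-likelihood test), with a median peak-to-trough fold of 1.64. The count ran from 178 to 1061 when 1 library was left out, and was 874 without the 3 libraries standing apart. The nearest sampled hour of the peak was 02:00 for 167 genes, 14:00 for 132, 10:00 for 70, 22:00 for 36, 18:00 for 14 and 06:00 for 4. Peaks fitted to all 9816 genes, called or not, lay nearest 02:00 in 21.2%, 14:00 in 17.8% and 06:00 in 11.1%, against 39.5%, 31.2% and 0.946% of the called genes. The 2 tests, made on the same libraries, shared 186 genes, where independent lists would share 9.70. A cosine is 1 form of a change over time, so sharing was built in and lends neither test support. Summing the libraries of each colony and time point gave 0 cosine genes in edgeR (972 at unadjusted p under 0.05). That fit recovered 53.7% of simulated genes given a 2-fold change and 5.97% at 1.5-fold, again with no difference between the colonies' courses. On the 27 libraries DESeq2 called 904 and limma-voom 396. Colony 1 alone gave 520 genes and colony 2 alone 1.

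**Figure D4:**
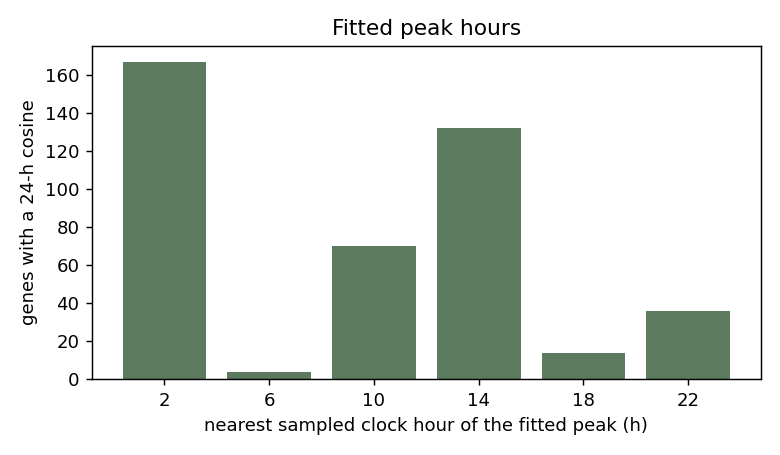
Number of genes with a 24-h cosine (vertical axis) by the sampled clock hour nearest their fitted peak (horizontal axis, h), over both colonies. The bars run from 4 genes at 6 h to 167 genes at 2 h, with 132 at 14 h.

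Among the lists fixed before the data were examined, members called over the 7 time points or with a cosine were few. Of the 3 heat shock and ER chaperones, Hsp90 changed over time and Hsc70-3 had a cosine (2 and 2 adjusted over the list alone). Of the 2 core clock genes, 0 passed over time and 1 had a cosine (1 and 1 adjusted over the list alone), and of the 4 photoreceptor genes, Uvop alone passed both. No member passed either test over all genes in the lists for memory signalling (7 genes), ecdysteroid and juvenile hormone (9), synaptic vesicle and active zone (5), neuropeptides (4), small Kenyon cells (3), large and middle Kenyon cells (3), or gland, fat body and hemolymph (16). Adjusted over the list alone, cosines were called for 3 synaptic vesicle genes, 2 small Kenyon cell genes and 1 ecdysteroid gene.

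The dopamine receptors Dop1 and Dop3 of the memory list had adjusted p = 0.331 and 0.571 over time, and DopR2, a dopamine receptor and the single Kenyon cell gene matched, 0.941. The neuropeptide gene Tk, also on the small Kenyon cell list, had 1397 ± 228 CPM at 14:00 and 989 ± 217 CPM at 10:00 (adjusted p = 0.400), NPF adjusted p = 0.382, and the ecdysone-regulated genes E74 and E75, the latter the single clock modulator matched, 0.353 and 0.866. Kr-h1, a juvenile hormone response gene, had adjusted p = 0.198, the synaptic genes Syx1A and brp 0.277 and 0.385, and Mblk-1 and Camkii of large Kenyon cells 0.4998 and 0.5997. Apid1 and Mrjp2 of the gland list had 0.249 and 0.334.

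Among the lists added from the gene symbols, the named chaperones held 1 gene that changed over time and 2 of 6 with a cosine, Hsc70-3 and Cdc37. A single gene passed over time for each of cyclic nucleotide and calcium signalling (Ip3k), opsins (Uvop), storage and hemolymph proteins (Fabp) and neuropeptides and their receptors (SIFR), and Eaat-2 alone had a cosine in the glutamate, GABA and histamine list. No gene passed either test in the lists for nicotinic acetylcholine receptors (nAChRa1 and nAChRa3, adjusted p = 0.0965 and 0.174 over time), biogenic amines (TyrR and 5-HT2alpha, 0.286 and 0.303), synaptic adhesion and release (NLG-5 and Dscam, 0.217 and 0.249), antioxidant enzymes (GstS1 and Cat, 0.0773 and 0.172), named ribosomal proteins (RpLP1, 0.214) or named mitochondrial genes (Ndufs5 and Cox6b1, 0.106 and 0.212). The same held for royal jelly and yellow genes (Y-f, 0.265), odorant-binding and chemosensory proteins (Obp3 and CSP1, 0.272 and 0.279), cuticle proteins (Apd-2 and CPR28, 0.312 and 0.447), troponins (TpnCIIIa and TpnCIIa, 0.294 and 0.313), immune genes (18-w, 0.283) and the noncoding RNAs Ks-1 and Kakusei (0.531 and 0.875). Over the 28 lists, Fisher's exact test (one-sided) found none enriched, the smallest p being 0.0248 for named chaperones with a cosine (Benjamini-Hochberg adjusted p = 0.693).

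The comparison of 14:00 with 02:00 set midday against midnight. All 9 genes that differed are known by identifier alone. LOC410368 was at 59.3 ± 19.1 CPM at 14:00 and 15.8 ± 4.27 CPM at 02:00 (log2 difference 1.91, SE 0.290, adjusted p = 0.00217), LOC552313 at 81.3 ± 12.1 and 33.8 ± 10.8 CPM, and LOC100577335 at 98.4 ± 28.8 and 40.9 ± 7.85 CPM. LOC412858, LOC726672 and LOC409949 were also higher at 14:00, with log2 differences of 1.07, SE 0.213, 0.99, SE 0.173 and 0.75, SE 0.151. LOC102653621 (-1.30, SE 0.261), LOC100576660 (-1.08, SE 0.208) and LOC726651 (-1.001, SE 0.192) were lower. LOC409949 lost its call in 18 of 39 alternative runs and LOC102653621 in 14. Cry2 had a log2 difference of -0.66, SE 0.482 (adjusted p = 0.594) and Hsp90 of 0.39, SE 0.190 (adjusted p = 0.387).

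Of 9816 genes, 6 were higher and 3 lower at 14:00 (edgeR's quasi-likelihood test), and the antioxidant enzymes lay higher as a group, with 9 of 10 above 0 and a median log2 difference of 0.25 (camera, adjusted p = 0.0237; adjusted p = 0.733 with an estimated correlation). No antioxidant gene passed over all genes, and 1 did adjusted over the list alone. Of the 10 fixed lists, heat shock and ER chaperones had 1 gene passing adjusted over the list alone and 0 over all genes. DESeq2 called 148 genes and limma-voom 9, and with the libraries of each colony and time point summed edgeR called 0 (386 at unadjusted p under 0.05). The count was 235 without 06:00 day 11 C2R2 and 2 without either 14:00 day 11 C1R1 or 02:00 day 12 C2R1. It was 576 without the 3 libraries standing apart, none of them of 14:00 or 02:00, and 1024 in quality-weighted limma-voom. The count of 9 therefore depends on libraries of other times in the shared fit.

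The comparison of 10:00 with 22:00 set morning against evening. Cry2 was at 4.20 ± 3.11 CPM at 10:00, lower than the 25.01 ± 3.86 CPM at 22:00 (log2 difference -2.57, SE 0.521, adjusted p = 0.00853), and in 10:00 day 11 C2R2 it had 0 counts, which allows up to 0.515 CPM. Adar (0.98, SE 0.186, adjusted p = 0.00502) and Hsp90 (0.78, SE 0.191, adjusted p = 0.0267) were higher at 10:00, and rtGEF was lower (-0.57, SE 0.116, adjusted p = 0.00835). In each of these genes all 4 libraries of 10:00 lay beyond all 4 of 22:00, which the rule for naming genes required. Among genes known by identifier, LOC408827 (2.60, SE 0.561), LOC410562 (2.12, SE 0.342) and LOC726302 (1.82, SE 0.424) were higher at 10:00, and LOC100578547 (-2.73, SE 0.629), LOC100576592 (-2.01, SE 0.548) and LOC726506 (-1.97, SE 0.487) lower. LOC100576592, with adjusted p = 0.0490, lost this call in 29 of 39 alternative runs.

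As groups in camera, the 2 core clock genes lay lower at 10:00, with a median log2 difference of -1.37 (adjusted p = 0.0328, and adjusted p = 0.249 with an estimated correlation). Cry2 alone was called, and Per had a log2 difference of -0.17, SE 0.231 (edgeR's quasi-likelihood test, adjusted p = 0.755). The 3 heat shock and ER chaperones lay higher, with a median of 0.27 and 1 gene called (adjusted p = 0.0328; adjusted p = 0.284 with an estimated correlation). Named chaperones, with 2 of 6 called higher, had a median of 0.21 (adjusted p = 0.0354; adjusted p = 0.299 with an estimated correlation). The glutamate, GABA and histamine genes had 9 of 11 above 0 and a median of 0.37 (adjusted p = 0.0328, and adjusted p = 0.113 with an estimated correlation). None of them passed over all genes, and 2 did adjusted over the list alone. That list includes Eaat-2, also the single gene matched in the glia list. All 6 troponins lay above 0, with a median of 1.19 (adjusted p = 0.0328; adjusted p = 0.697 with an estimated correlation), although none passed on its own over all genes. TpnCIIIa had 285 CPM in 10:00 day 11 C2R1, 56.5 CPM in 10:00 day 11 C2R2, and 40.6 and 27.7 CPM in the colony 1 libraries of 10:00. Adjusted over the list alone, 1 core clock gene, 1 heat shock gene, 1 photoreceptor gene and 1 neuropeptide gene passed, and 0 in the other 6 fixed lists tested.

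Of 9816 genes, 92 were higher and 120 lower at 10:00 (edgeR's quasi-likelihood test), and DESeq2 called 520. The count ran from 78 to 535 when 1 library was left out. Both colony 2 libraries of 10:00 stood apart and held 5589770 and 6242597 counts. Without the 3 libraries standing apart 70 genes were called, 50 of them shared with the 212. Colony 1 alone gave 415, with 141 shared. With the libraries of each colony and time point summed edgeR called 0 genes (668 at unadjusted p under 0.05). That fit recovered 47.8% of simulated genes given a 2-fold change and 2.985% at 1.5-fold, with no difference between the colonies' courses in the simulation.

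The comparison of 06:00 on day 12 with 06:00 on day 11 set the same clock hour a day apart. Cry2 had 12.2 ± 3.61 CPM on day 12 and 10.0 ± 5.27 CPM on day 11 (adjusted p = 0.824). Per had 28.1 ± 8.65 and 21.1 ± 9.23 CPM (adjusted p = 0.454), and Hsp90 2280 ± 713 and 2154 ± 713 CPM (adjusted p = 0.941). SIFR had 16.0 ± 4.46 and 39.6 ± 25.8 CPM (log2 difference -1.28, SE 0.320, adjusted p = 0.369). edgeR's quasi-likelihood test called 0 of 9816 genes, with 1138 at unadjusted p under 0.05 and a smallest adjusted p of 0.369, and DESeq2 and limma-voom called 0 and 0. Without 06:00 day 11 C1R1 edgeR called 366 genes, and quality-weighted limma-voom called 3.

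The 2 colonies were compared over all time points. RpLP1, a protein of the ribosomal stalk, was at 575 ± 272 CPM in colony 2 (n = 13) and 298 ± 21.1 CPM in colony 1 (n = 14), with a log2 difference of 0.88, SE 0.132 (adjusted p = 1.11e-04). Rpl41, another ribosomal protein, and Ndufs5, a subunit of respiratory complex I, were also higher in colony 2 (0.77, SE 0.124 and 0.76, SE 0.150), as were Fabp (0.72, SE 0.117) and the cuticle protein CPR4 (0.85, SE 0.137). Lower in colony 2 were the cuticle protein CPR6 (-1.32, SE 0.347), Psq, which encodes a DNA-binding protein (-0.91, SE 0.175), the neuroligin NLG-5 (-0.88, SE 0.178), the dopamine receptor Dop3 (-0.75, SE 0.166) and the noncoding RNA Ancr-1 (-0.75, SE 0.163). The rule for naming genes required the same direction at all 7 time points.

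All 7 named ribosomal proteins were higher in colony 2, with a median log2 difference of 0.62 (camera, adjusted p = 1.89e-10; adjusted p = 0.294 with an estimated correlation). The 17 named ribosomal and mitochondrial genes together had a median log2 difference of 0.56, and of 0.35 without the 3 libraries standing apart, with 14 of 17 above 0. By time point their median was 1.37 at 06:00 of day 11 and 1.04 at 10:00, the times of those 3 libraries, and 0.09 to 0.57 at the other 5. Of 10 named mitochondrial genes, 7 were called higher and 9 lay above 0, with a median of 0.46 (adjusted p = 3.85e-05; adjusted p = 0.782 with an estimated correlation). Of 10 antioxidant enzymes, 5 were called higher and all 10 lay above 0, with a median of 0.46 (adjusted p = 0.000568; adjusted p = 0.782 with an estimated correlation). Of the 7 memory signalling genes, 3 were called lower, 1 lay above 0 and 3 passed adjusted over the list alone. Called photoreceptor genes were 2 higher and 1 lower, the gland, fat body and hemolymph list 1 higher and 2 lower of 16, and the synaptic vesicle list 1 higher (3, 3 and 1 adjusted over the list alone). The other 6 fixed lists had 0 called both ways. Among lists of the other cell types, troponins had 0 called, with a median of 0.91, and cuticle proteins 1 higher and 1 lower of 14.

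Of 9816 genes, 1045 were higher and 1404 lower in colony 2 (edgeR's quasi-likelihood test). Of these, 1031 averaged 10 CPM or more and differed in 1 direction at all 7 time points, 415 upward and 616 downward. Colony cannot be told apart from experiment, since each was a separate run. Summing the libraries of each colony and time point left 24 genes. That fit recovered 70.1% of simulated genes given a 2-fold change, with no difference between the colonies' courses in the simulation. Leaving out the 3 libraries standing apart gave 1227.

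Whether the time course differed between colonies was asked by an interaction test. The 5 genes with the smallest p are known by identifier alone. Levels given for them are means over all time points, while each p is for a difference in course, not in level. The largest minus the smallest colony difference over time was a log2 of 3.71 for LOC409953 and 4.06 for LOC725646. In the alternative run with the lowest value it was 0.711 and 0.6005. LOC409953 was at 397 ± 70.9 CPM in colony 1 and 268 ± 123 CPM in colony 2 (adjusted p = 2.54e-06), and LOC725646 at 125 ± 21.5 and 101 ± 40.5 CPM (adjusted p = 6.30e-06). LOC410558, LOC726262 and LOC413940 shared an adjusted p of 4.51e-05. edgeR called 2209 of 9816 genes, and 215 without 06:00 day 11 C2R2, the single colony 2 library of its time point. Without that library the colonies were no longer compared at 06:00 of day 11. Limma-voom with quality weights called 2770 genes when the weights came from the interaction fit, in which that library is alone in its cell, and 0 when they came from the fit without interaction (210 at unadjusted p under 0.05), where its weight was 0.0936. In that library the small Kenyon cell genes had a median log2 difference of -1.63 from the rest of colony 2, the large and middle Kenyon cell genes -1.63, and the photoreceptor genes 1.05.

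For the cosine, LOC409753 and LOC410259 differed between colonies in daily course by the interaction test (adjusted p = 0.0417 and 0.0417). The difference had a peak-to-trough log2 size of 1.36 and 1.54. Means over all time points, which this test does not compare, were 73.5 ± 10.8 and 114 ± 38.6 CPM for LOC409753 in colonies 1 and 2. For LOC410259 they were 46.3 ± 9.05 and 66.7 ± 22.0 CPM. Over 37 alternative runs LOC410259 lost the call in 21 and LOC409753 in 19. These 2 were the calls of edgeR's quasi-likelihood test, against 83 in DESeq2 and 4 in limma-voom. The count was 0 with libraries thinned to the smallest total (1237 at unadjusted p under 0.05) and 124 without the 3 libraries standing apart.

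The median, mean and camera direction of a list differed in sign for several lists that did not pass. At 14:00 against 02:00 these were ecdysteroid and juvenile hormone, neuropeptides, neuropeptides and their receptors, cyclic nucleotide and calcium signalling, odorant-binding proteins, cuticle proteins and noncoding RNAs. At 10:00 against 22:00 they were synaptic vesicle, synaptic adhesion and odorant-binding proteins, and between colonies ecdysteroid and juvenile hormone, synaptic vesicle, nicotinic receptors, odorant-binding proteins, immune and storage genes. Neuropeptides at 14:00 against 02:00 had a median log2 difference of 0.11, a mean of -0.32 and an upward direction in camera.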

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

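Of the tests below, those on the interaction, on depth and colony 1 for 10:00 against 22:00, and the choice of thinning and of 3 libraries standing apart were made after the result was seen. In 6 of 186 groups of 4 libraries 1 library lay far from the rest, where chance flags about 1 in 20 groups. The total count of 22:00 day 11 C2R2 was 5837096, against 10446636 to 10846551 in the other libraries of that time. Cry2 had 30.8 CPM in 22:00 day 11 C2R2, against 22.4 to 23.6 CPM. Hsp90 had 3343 CPM in 06:00 day 12 C2R1, against 1854 to 2036 CPM. LOC113219162 had 2.99 CPM in 22:00 day 11 C2R2, against 7.21 to 7.78 CPM. LOC726672 had 104.9 CPM in 14:00 day 11 C2R1, against 80.7 to 81.8 CPM. LOC409949 had 282 CPM in 06:00 day 12 C2R2, against 375 to 392 CPM. The 24-h cosine differed between colonies by the interaction test in 2 genes.

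The interaction of colony and time was called for 2209 genes, a difference between the colonies' courses found by a test of that difference. Thinning to the smallest library total gave 2148 genes, which argues against unequal sampling noise from fewer reads in colony 2 as the whole cause. Thinning keeps each gene's expected share of counts, so other effects of depth were not tested. Without 06:00 day 11 C2R2, the single colony 2 library of its time, 215 genes were called, so 1 library may carry most of the count. The fit without it does not compare the colonies at 06:00 of day 11. It cannot tell an unusual library from a colony difference at that time. In that library both Kenyon cell lists lay at a median log2 difference of -1.63 from the rest of colony 2, while every list of other cell types lay above 0, the lowest being cuticle proteins at 0.48 (Eaat-2 was at 211 CPM and TpnCIIIa at 98.5 CPM), so a smaller share of Kenyon cells in that capture may contribute. A difference between colonies in daily course stays open, with 9 genes called without the 3 libraries standing apart. The 100 regroupings shuffled colony within time points and reached 3313 genes, so chance could not be excluded. They also removed the overall colony difference and can leave 06:00 day 11 C2R2 alone again, so they do not show chance to be the cause.

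For 10:00 against 22:00, 212 genes were called, and both colony 2 libraries of 10:00 stood apart. Colony 1 alone gave 415 genes, 141 of them among the 212, which argues against those libraries as the whole cause. The common biological coefficient of variation was 0.179 in colony 1 and 0.329 over both colonies, so these counts are not directly comparable. Thinned counts gave 221 genes, which argues against unequal sampling noise as the cause. As thinning keeps expected shares of counts, other effects of depth were not tested. Of the 415 genes, 83.13% had the same sign in colony 2, in line with a change shared by both colonies, although the other 10 pairs of times gave 40.72% to 87.23%. Without the 3 libraries standing apart 70 genes were called. A daily change therefore remains a hypothesis, found and tested on the same libraries.

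The 17 named ribosomal and mitochondrial genes had a median log2 difference of 0.56 in favour of colony 2. Thinned counts gave 0.57 (bootstrap SE over the 17 genes 0.0619). Thinning keeps each gene's expected share of counts, so this median could hardly move, and depth as the cause stays open. Leaving out the 3 libraries standing apart gave 0.35 (bootstrap SE 0.0454), above the 0.28 under which they would make up most of it, but the genes are not independent, so this SE may be too small and that explanation stays open. The median was above 0 at 7 of 7 time points, with 1.37 at 06:00 of day 11 and 1.04 at 10:00, the times of those libraries, and 0.09 to 0.57 at the other 5. Colony and experiment cannot be told apart, because each colony was a separate run, and a difference between colonies stays open as well.

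Other regroupings of the same libraries were compared with the real one. They treat every library as independent, and edgeR on libraries summed per colony and time point called 0 genes for the time test, the cosine and 10:00 against 22:00 (325, 972 and 668 at unadjusted p under 0.05). If libraries are independent, chance could be excluded for the time test (225 genes, highest other 1) and the cosine (423, highest other 141). Colony lay above its regroupings (2449, highest other 0), and summed libraries gave 24 genes. With a single experiment per colony, a chance difference between any 2 colonies cannot be excluded. The cosine interaction also lay above its regroupings, but by a single gene (2, highest other 1), and edgeR called 0 in thinned libraries (1237 at unadjusted p under 0.05). Its regroupings shuffled colony within time points, which also removed the overall colony difference, so they cannot decide on courses alone. Chance could not be excluded for 14:00 against 02:00 (9, highest other 24).

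The regroupings of the time contrasts also mixed libraries of both colonies. For 10:00 against 22:00 the real split (212) lay above all others of the 35 (highest other 2), a comparison that ignores colony. For this contrast and 14:00 against 02:00, 18 of the 35 kept the numbers per colony, with highest other counts of 2 and 0, and these are too few for a share under 0.05. For 06:00 against 06:00 the comparison decides nothing, since all 35 regroupings call at least the real 0 genes (highest other 265).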

How the results depend on the processing

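Quality weights, thinning, the 3 libraries left out, contrasts in colony 1 alone, fry and the estimated correlation were chosen after the data were seen. Unless a construction is named, the cause was not tested. Size factors of DESeq2, no filter and the stricter filter moved no count beyond 1.5 times. No named gene reversed in a time contrast or between colonies. Ranges over time and sizes of interactions have no sign, so no reversal could show there. Calls were lost, among them the time call of Uvop, SPG11 and LOC724367 in 25 of 41 alternative runs each. Of the same 41 runs, LOC113219162 lost its time call in 22, Ip3k in 21 and AChE-2 in 12. Over 39 runs the call at 10:00 against 22:00 of LOC100576592 was lost in 29. Time calls were also gained, by Cry2 in 10 and GstS1 in 7 of 41 runs, and over all named genes and runs 162 time calls were lost and 78 gained. Sums were not run for the interactions, nor set tests for lists with fewer than 2 matched genes.

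In the order time, cosine, 14:00 against 02:00 and 10:00 against 22:00, DESeq2 called 808, 904, 148 and 520 genes, no colony term 65, 187, 2 and 79, and weighted limma-voom 1865, 1207, 1024 and 1003, with 3 for 06:00 against 06:00. Summed libraries gave 0, 0, 0 and 0 in edgeR (325, 972, 386 and 668 at unadjusted p under 0.05), and 24 for colony. The cosine interaction had 83 genes in DESeq2, 4 in limma-voom, 67 with weights, 12 with weights from the fit without interaction, 124 without the 3 libraries and 0 thinned (1237 at unadjusted p under 0.05). The interaction had 0 with those last weights (210 at unadjusted p under 0.05). It had 9 without the 3 libraries, a fit with no colony 2 library at 06:00 of day 11 or at 10:00. Leaving out those 3 also gave 874 for the cosine, 576 for 14:00 against 02:00, 70 for 10:00 against 22:00 and 1227 for colony. Thinning gave 5 for 14:00 against 02:00. Without 06:00 of day 11, time had 548 and the cosine 817. Time had 368 in colony 1 alone and 2162 in colony 2 alone, where 06:00 of day 11 is the single library C2R2, assumed to vary like the others, and the cosine had 1; colony 1 alone had 21 for 14:00 against 02:00 and 415 for 10:00 against 22:00.

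With the replicate block, time had 143 genes; the other counts stayed within 1.5 times. Replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.07 to 0.24 over 21 pairs in colony 1 and at -0.17 to 0.16 over 15 pairs in colony 2.

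Camera with an estimated correlation ended each call, at adjusted p = 0.733 (antioxidant, 14:00 against 02:00), 0.249 (core clock), 0.284 (heat shock), 0.113 (glutamate, GABA and histamine), 0.299 (chaperones) and 0.697 (troponins) for 10:00 against 22:00, and 0.782 (antioxidant), 0.294 (ribosomal) and 0.782 (mitochondrial) for colony. Fry, which does not compare a list with other genes, ended antioxidant at 14:00 against 02:00 (0.388) and troponins (0.364). It called glutamate, GABA and histamine at 14:00 against 02:00 (0.00238) and, for colony, memory signalling (0.0472), neuropeptides (0.0135), biogenic amines (0.0472) and neuropeptides with receptors (0.0275). Its direction was opposite to camera's, uncalled by both, for odorant-binding proteins at 14:00 against 02:00 (0.965), for gland (0.918), synaptic adhesion (0.955) and storage (0.912) at 10:00 against 22:00, and for ecdysteroid (0.979), synaptic vesicle (0.979), cuticle (0.958), immune (0.626) and storage (0.836) between colonies.

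Leaving out 1 library at a time, time ranged from 105 to 569: without C1R1 or C2R2 of 06:00 day 11 569 and 523, C1R2, C2R1 or C2R2 of 10:00 107, 110 and 105, C1R1 or C1R2 of 14:00 137 and 145, C1R2 or C2R1 of 22:00 127 and 145, C2R1 or C2R2 of 02:00 133 and 142, and C2R1 of 06:00 day 12 135. The cosine ranged from 178 to 1061: 1061 without 06:00 day 11 C2R2, 207 without 10:00 C1R2, and 178 and 249 without 02:00 C2R1 and C2R2. For 14:00 against 02:00 the range was 2 to 235: without C1R1 or C2R2 of 06:00 day 11 24 and 235, 10:00 C2R1 18, C1R1 or C1R2 of 14:00 2 and 5, C1R1, C1R2, C2R1 or C2R2 of 02:00 5, 98, 2 and 5, and 06:00 day 12 C2R2 14. For 10:00 against 22:00 it was 78 to 535: 535 without 06:00 day 11 C2R2, 122 and 96 without 10:00 C2R1 and C2R2, and 137, 78, 85 and 121 without C1R1, C1R2, C2R1 and C2R2 of 22:00. For 06:00 against 06:00 it was 0 to 366, the latter without 06:00 day 11 C1R1, for colony 2044 to 2687, and for the interaction 215 to 3134, with 1332 and 215 without 06:00 day 11 C1R1 and C2R2. The cosine interaction ranged from 0 to 17, within 1.5 times in 4 of 27 runs, with 17 without 14:00 C2R1. Leaving C1R1 or C1R2 of 06:00 day 11 out keeps 1 colony 1 library there, assumed to vary like the others. Leaving C2R2 of that time out keeps no colony 2 library there, so the interaction then does not compare the colonies at that time.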
